A study of Mus musculus with 157 samples.

How the data were processed

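Bulk RNA-seq of 157 mouse libraries was re-analysed from the deposited gene tables. Per the labels' protocols, total RNA was isolated with the RNeasy Plus Mini kit from at least 5000 sorted thymocytes, or from a larger number of lymphoma cells, and sequenced on the HiSeq2000. Tumours were unsorted unless the label says otherwise. Per the submitters' processing notes, reads were checked with FastQC, aligned to GRCm38 with STAR 2.5.3a and quantified with RSEM 1.3.0. The authors deposited 2 tables of expected counts (RSEM estimated counts per gene), whose values were all whole numbers. Strandedness and the authors' annotation release are not given in the sources used here. Names, positions and gene types came from GENCODE M21, which may not be the authors' annotation. Each table had 50686 genes, of which 50376 had a symbol. No column was left without a sample and no pair of libraries was identical. The tables came from an earlier and a later run, and every test stayed within 1 run.

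Groups followed the labels, and the comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. Genes were kept by filterByExpr and scaled by TMM, and groups were compared with edgeR 4.0.16 quasi-likelihood fits (robust, 2-sided) in R 4.3.3. Adjusted p-values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Values after ± are SE for fold changes (the log2 fold change divided by the square root of F) and SD for levels. CPM used TMM-scaled totals. The interaction of genotype and stage was an F-test over DN1, DN3, DN4 and DP. DN2 was left out because 1 library was D/AAA. The 2 MYCChr6 groups of 2 libraries and the p53(-/-) tumour were left out of tests because of their size. A gene at 0 counts in 1 group was given a bound against a floor of 3 counts per library.

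In each comparison up to 10 genes with the largest positive and 10 with the largest negative fold change were named among those with adjusted p under 0.05, mean CPM of at least 5 in 1 group and at least 80% of first-group libraries on the same side of the second group's median. Xist, Tsix, Y-linked, receptor and immunoglobulin segments, mitochondrial genes and identifier-only names were left out of this choice. Cdc20, Trp53 and Myc were always named. The 34 fixed lists (22 of pathways and stages, 12 of cell types) were tested with limma 3.58.1 camera at the preset correlation 0.01 and with an estimated correlation, and with fry, a self-contained rotation test. Members were also counted after adjustment over the list alone. The values of some list members are not reported here.

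Chromosome scores used log2 CPM (prior count 2) of genes with a mean of at least 10 CPM, centred per gene on all libraries of a comparison or, for gains, on the control group. Groups were compared by exact permutation where a group had under 10 libraries and otherwise by 100000 resamples, 2-sided, with Benjamini-Hochberg over 20 chromosomes. Gains were scores above 0.292 and losses scores below -0.5. The top Trbv share was taken in libraries with at least 100 Trbv counts.

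Alternatives were DESeq2 1.42.0, relative log expression factors, no low-count filter, limma voom with sample quality weights, 1 fit of all sorted libraries, libraries with under the median total divided by 3 left out, each library of groups of up to 5 left out in turn, genes down to 1 CPM, a trimmed mean (10% at each end), centring on the chromosome scores, a reference mean with 3 SD, Trav genes, and at least 500 Trbv counts. Analyses within 1 block of the earlier run, without libraries that stood apart (unsorted early tumours nearest to DN3 and DN4 or with the most globin, non-tumoral D/AAA libraries with chromosome 15 gains, the LCK tumour with the most immunoglobulin), of marker and named gene levels without the library at the highest value, and of chromosome bins with genes down to 1 CPM, with and without T cell receptor segments, were added after seeing the data. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

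Each gene comparison was tested on simulated data of the same size and depth. Of 100 genes changed 4-fold, edgeR recovered 65% (DN1), 72% (DN3), 71% (DN4), 75% (DP) and 72% (sorted DP early tumours). It found 73% (unsorted early tumours), 73% (thymus), 76% (tumours against thymus), 80% (tumours labelled p53(+/D)) and 58% (RERT2 MYCChr6 tumours). It found 79% (LCK D/AAA MYCChr6 tumours), 34% (LCK MYCChr6 tumours by genotype) and 0% (RERT2 MYCChr6 tumours against thymus). Of 100 at 2-fold it found 0% to 53%. Chromosome 15 raised 1.5-fold was recovered in every comparison tested, with up to 6 other chromosomes called.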

Results

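RNA was sequenced from 157 mouse libraries in 23 groups. The Cdc20 gene product activates the anaphase-promoting complex at the metaphase to anaphase transition, and its AAA form is one that the checkpoint protein Mad2 cannot bind. Libraries labelled Cdc20(D/AAA), the aneuploid genotype of the series, were set against libraries labelled Cdc20(+/D). RERT2, LCK and CD4 named the driver of each mouse line, and MYCChr6 marked mice with human MYC inserted on mouse chromosome 6. Early T cell progenitors were sorted by stage, from the double negative stages DN1 to DN4 to the double positive stage (DP). The earlier run held 81 libraries. They were sorted RERT2 +/D cells at DN1 (n = 6), DN2 (8), DN3 (8), DN4 (8) and DP (7), sorted RERT2 D/AAA cells at DN1 (9), DN2 (1), DN3 (5), DN4 (6) and DP (11), RERT2 D/AAA early tumours sorted as DP (5) and RERT2 D/AAA early tumours with no sorted population named (7). The later run held 76 libraries. They were RERT2 non-tumoral thymus of +/D (6), D/AAA (9), +/D MYCChr6 (2) and D/AAA MYCChr6 (3) mice, and tumours of RERT2 D/AAA (22), RERT2 D/AAA p53(+/D) (10), RERT2 D/AAA MYCChr6 (3), LCK D/AAA MYCChr6 (14), LCK +/D MYCChr6 (4), CD4 D/AAA MYCChr6 (2) and p53(-/-) (1) mice. The earlier run was cut here by library order and depth into unlabelled blocks. Total counts ran from 3784797 to 11595463 in block 1 (56 libraries, all +/D among them). In block 2 (25 libraries, all D/AAA) they ran from 21199 (sorted DN1 D/AAA replicate 8, others at least 2701382) to 5373182. In the later run totals ran from 1708619 to 8009572. Ranges were 2461375 to 6639518 in RERT2 D/AAA tumours, 2673329 to 6209705 in D/AAA thymus, 4564661 to 6749336 in +/D thymus, 1708619 to 7600025 in tumours labelled p53(+/D) and 4237526 to 7038313 in LCK D/AAA MYCChr6 tumours. The labels do not say whether samples are separate animals, so p-values measure the spread between these samples. The gene CT010467.1, which overlaps ribosomal RNA sequence, took 40.5% ± 5.53 (SD) of counts in the later run and 0.745% ± 0.347 in the earlier run, and within the later run 48.7% ± 2.89 in +/D thymus, 48.1% ± 3.79 in D/AAA thymus, 40.4% ± 2.71 in RERT2 D/AAA tumours, 36.5% ± 1.86 in tumours labelled p53(+/D), 36.0% ± 3.402 in LCK D/AAA MYCChr6 tumours, and 44.3% ± 2.75 and 35.2% ± 3.34 in D/AAA MYCChr6 thymus and tumours. No test crossed the runs.

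The genes named by the labels were Cdc20 (GRCm38 chromosome 4, 118432901 to 118437352), Trp53 (chromosome 11, 69580359 to 69591873) and Myc (chromosome 15, 61985391 to 61990374), all protein-coding. For Cdc20 the gene count cannot show the AAA form. For Cdc20, in sorted +/D and D/AAA cells its mean CPM (± SD) was 19.3 ± 6.54 and 19.6 ± 8.72 at DN1, 171 ± 62.0 and 243 ± 62.6 at DN3, 270.5 ± 70.1 and 286 ± 69.5 at DN4 and 178 ± 70.0 and 206 ± 90.6 at DP, with 160 ± 96.0 in +/D DN2 cells and 248 in the lone D/AAA DN2 library. Early tumours had 267 ± 71.7 (sorted DP) and 79.6 ± 109.6 (unsorted). Thymus had 41.7 ± 4.89 (+/D), 49.4 ± 27.1 (D/AAA), 35.3 ± 4.06 (+/D MYCChr6) and 64.4 ± 12.2 (D/AAA MYCChr6). Tumours had 78.6 ± 27.4 (RERT2 D/AAA), 90.5 ± 28.3 (p53(+/D)), 60.2 ± 13.3 (RERT2 MYCChr6), 57.9 ± 26.1 (LCK D/AAA MYCChr6), 47.0 ± 17.7 (LCK +/D MYCChr6), 85.2 ± 24.6 (CD4 MYCChr6) and 188 (p53(-/-)). For Trp53, in sorted +/D and D/AAA cells its mean CPM (± SD) was 322 ± 45.2 and 296 ± 117 at DN1, 342 ± 32.0 and 386 ± 27.8 at DN3, 394 ± 36.0 and 357 ± 44.6 at DN4 and 208 ± 68.6 and 220.1 ± 81.5 at DP, with 421 ± 78.2 in +/D DN2 cells and 306 in the lone D/AAA DN2 library. Early tumours had 316 ± 168 (sorted DP) and 300.3 ± 41.8 (unsorted). Thymus had 117 ± 17.8 (+/D), 159.5 ± 50.9 (D/AAA), 134 ± 39.2 (+/D MYCChr6) and 91.8 ± 44.6 (D/AAA MYCChr6). Tumours had 164 ± 57.0 (RERT2 D/AAA), 13.8 ± 7.28 (p53(+/D)), 138 ± 34.9 (RERT2 MYCChr6), 149 ± 40.5 (LCK D/AAA MYCChr6), 156 ± 22.4 (LCK +/D MYCChr6), 187 ± 13.2 (CD4 MYCChr6) and 17.8 (p53(-/-)). The 10 tumours labelled p53(+/D) ranged from 7.56 to 27.5 CPM, all below the lowest of the 22 RERT2 D/AAA tumours (31.6). These levels lay around that of the p53(-/-) tumour (17.8). The label gives a genotype and not the state of the + allele in each tumour, which was not tested. For Myc, in sorted +/D and D/AAA cells its mean CPM (± SD) was 257 ± 43.4 and 224 ± 56.0 at DN1, 503 ± 84.1 and 459 ± 39.5 at DN3, 449 ± 56.6 and 386 ± 82.6 at DN4 and 21.9 ± 10.2 and 79 ± 80.4 at DP, with 392 ± 51.7 in +/D DN2 cells and 249.6 in the lone D/AAA DN2 library. Early tumours had 244 ± 131 (sorted DP) and 249.8 ± 96.8 (unsorted). Thymus had 57.2 ± 21 (+/D), 148 ± 97.0 (D/AAA), 61.8 ± 16.5 (+/D MYCChr6) and 119 ± 86.8 (D/AAA MYCChr6). Tumours had 175 ± 75.5 (RERT2 D/AAA), 199 ± 51.2 (p53(+/D)), 85.9 ± 17.9 (RERT2 MYCChr6), 97.9 ± 30.5 (LCK D/AAA MYCChr6), 101 ± 76.4 (LCK +/D MYCChr6), 159.6 ± 51.0 (CD4 MYCChr6) and 135 (p53(-/-)).

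In sorted +/D cells Cd44 averaged 201 ± 25.1 CPM at DN1 and 0.401 ± 0.455 at DN3. The interleukin-2 receptor gene Il2ra averaged 650.3 ± 94 at DN2, 492 ± 161 at DN3 and 8.34 ± 5.14 at DN4. Kit was highest at DN2 (64.3 ± 24.8) among the 5 stages. The pre-T cell receptor gene Ptcra averaged 608 ± 106 at DN3. At DP, Cd4 averaged 1870 ± 158, Cd8a 2238 ± 474, Cd8b1 3100 ± 628 and Rag1 449 ± 219.6. In D/AAA cells Il2ra averaged 494 ± 125 at DN3 and Cd4 1285 ± 449 at DP. At DN1 the shallow D/AAA replicate 8 stood apart, with Cd8b1 at 738 CPM and Rag1 at 154 CPM. Without it the other 8 libraries averaged 8.43 ± 5.18 and 0.714 ± 0.728 CPM, against 9.23 ± 5.39 and 0.512 ± 0.605 CPM in +/D. Receptor genes went against reading the DN1 label as early progenitors alone. All 6 +/D DN1 libraries were led by Trbv13-2 (33.99% to 46.95% of Trbv counts) and by Trav11 (38.3% to 68.4% of Trav counts), the variable genes of invariant NKT cells. They had 3257 to 5177 Trbv counts, against 503 to 1676 at DN2. In D/AAA DN1 cells Trbv13-2 led 8 of 8 libraries with at least 100 Trbv counts.

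The first question was whether the D/AAA genotype changed expression within a sorted stage. At DN1 (D/AAA n = 9, +/D n = 6) Cdc20 (-0.06 ± 0.39 log2 fold change ± SE), Trp53 (-0.03 ± 0.24) and Myc (-0.14 ± 0.17) did not pass. Of gamma delta T cell genes 2 of 9 were lower adjusted over the list alone and 0 over all genes, with Cd163l1 (-1.40 ± 0.38) (camera adjusted p = 3.3e-05, adjusted p = 0.259 with an estimated correlation). Dendritic cell genes had a median log2 fold change of -0.34 over 11 members (camera adjusted p = 0.00254, adjusted p = 0.828 with an estimated correlation). Of the NK and innate lymphoid list, 2 of 10 were lower adjusted over the list alone, with Ncr1 (-1.0 ± 0.30) and Eomes (-1.15 ± 0.39). Over all genes, edgeR called 0 (353 of 12822 genes had an unadjusted p under 0.05; DESeq2 8, limma voom with quality weights 0), without the shallow replicate 8 it called 1, within block 1 (6 against 6) 1, and in 1 fit of all sorted libraries 63. At DN3 (5 against 8) Cdc20 (0.52 ± 0.24, adjusted p = 0.995), Trp53 (0.20 ± 0.11) and Myc (-0.12 ± 0.13) did not pass either. Mitotic genes leaned higher, with Ect2 (0.66 ± 0.21) and Tpx2 (0.50 ± 0.22), but 0 of 30 passed even adjusted over the list alone (camera adjusted p = 2.2e-14, adjusted p = 0.424 with an estimated correlation). Over all genes, edgeR called 0 (549 of 12912 genes had an unadjusted p under 0.05; DESeq2 13, limma voom with quality weights 2), again 0 within block 1 (4 against 8), and 3 in 1 fit of all sorted libraries. Leaving out D/AAA replicate 1, 2, 3 or 4 gave 1, 2, 1 or 4 genes.

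At DN4 (6 against 8) the one gene called was Gm10182, a processed pseudogene on chromosome 9 (22321105 to 22321377), named after its values were seen. It had 0 counts in all 6 D/AAA libraries and 236 to 910 counts in the 8 +/D libraries (58.6 ± 15.9 CPM, SD), so it was at least 112-fold lower against a floor of 3 counts per library (adjusted p = 3.3e-08). Red cell genes stood higher: 6 of 6 higher and 0 lower adjusted over the list alone, 0 over all genes, with Hba-a2 (4.35 ± 0.80) and Hba-a1 (4.29 ± 0.80) (camera adjusted p = 2.0e-19, 0.0208 with an estimated correlation). Hba-a1 and Hba-a2, and likewise Hbb-bs and Hbb-bt, are near-identical copies whose shares are uncertain. Globin genes took 1.65% ± 1.25 of counts in D/AAA and 0.0824% ± 0.0948 in +/D libraries. Gamma delta T cell genes gave 4 of 9 higher and 0 lower adjusted over the list alone, 0 over all genes, with Tcrg-C2 (0.86 ± 0.21) and Tcrg-C1 (0.92 ± 0.24) (camera adjusted p = 4.6e-10, adjusted p = 0.0559 with an estimated correlation). Cdc20 (0.13 ± 0.17), Trp53 (-0.08 ± 0.11) and Myc (-0.16 ± 0.13) did not pass. In all 798 genes had an unadjusted p under 0.05 (DESeq2 26, limma voom with quality weights 1). Within block 1 (4 against 8) Gm10182 was again the one gene called, and 1 fit of all sorted libraries called 4.

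At DP (11 against 7) Gm10182 was again the one gene called by edgeR on these libraries, lower in D/AAA, while 1 fit of all sorted libraries called 255 genes (210 higher). For Gm10182, 10 of the 11 D/AAA libraries had 0 counts and the other had 1 count, against 9 to 366 counts in +/D (adjusted p = 9.9e-10). Myc averaged 85.8 ± 90.1 CPM in D/AAA and 22.8 ± 10.4 in +/D, a difference of 1.91 ± 0.55 with 9 of 11 libraries above the +/D median that did not pass (adjusted p = 0.274) but did in that fit. Cdc20 (0.25 ± 0.26) and Trp53 (0.13 ± 0.21) did not pass. Genes of MYC targets and ribosome biogenesis gave 12 of 31 higher and 0 lower adjusted over the list alone, 0 over all genes, with Gnl3 (1.89 ± 0.47) and Nop58 (1.39 ± 0.38) (camera adjusted p = 4.3e-08, adjusted p = 0.520 with an estimated correlation). Mature thymocyte genes gave 4 of 20 higher and 1 lower adjusted over the list alone, 0 over all genes, with Itgb7 (1.73 ± 0.41) and Itm2a (1.12 ± 0.28). DN2 and DN3 genes gave 3 of 12 higher and 0 lower adjusted over the list alone, 0 over all genes, with Dtx1 (2.10 ± 0.47) and Hes1 (4.18 ± 1.24). Replicates 1 and 5 of the D/AAA cells stood apart, with chromosome 15 scores of 0.80 and 0.54, Myc at 293 and 112 CPM, and 58.4% (Trbv15) and 29.0% (Trbv3) of Trbv counts in 1 gene. Without them Myc averaged 55.9 ± 40.1 against 23.1 ± 10.6 CPM (1.27 ± 0.42, adjusted p = 0.300), and adjusted over the list alone 5 of 31 MYC target, 2 of 20 mature and 2 of 11 DN2 and DN3 genes were higher. Double positive thymocyte genes had a median of -0.24, with 0 of 20 past the test on either count (camera adjusted p = 2.7e-04, adjusted p = 0.520 with an estimated correlation). DESeq2 called 68 genes (55 higher), limma voom with quality weights 8, and edgeR within block 1 (5 against 7) 5 (4 higher), while 1325 genes had an unadjusted p under 0.05 with all libraries. Whether the genotype difference depended on stage was tested over DN1, DN3, DN4 and DP at once, and 22 genes passed. They were Colq, Psrc1, Sdc1, Gm10182, Slamf9, Ifit3b, Kif7, P2rx1, Stk36, Iqcd, Zfp365, Cd160, Emb, Trgj1, Spin2c, Fn3k, Gm20481, Cebpd, Hk2, Gm10433, Bst1 and Myc. Psrc1 differed by 5.38 ± 1.13 at DN1 and 0.01 ± 0.40 at DP. Myc differed by -0.16 ± 0.13 at DN4 and 1.91 ± 0.55 at DP, Hk2 by 0.03 ± 0.28 at DN4 and 3.44 ± 0.94 at DP, Cd160 by -0.55 ± 0.26 at DN1 and 2.92 ± 0.83 at DP, and Sdc1 by -2.41 ± 0.51 at DN1 and 7.89 ± 1.51 at DP. With DN4 and DP alone 0 genes passed, and within block 1 51.

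Early tumour cells sorted as DP (n = 5) were set against non-tumoral D/AAA DP cells (n = 11). Nucleolar and ribosome biogenesis genes stood higher: 25 of 31 higher and 0 lower adjusted over the list alone, 0 over all genes, with Ncl (1.33 ± 0.33) and Mybbp1a (1.29 ± 0.32) (camera adjusted p = 7.8e-15, adjusted p = 0.402 with an estimated correlation). Cytosolic ribosomal protein genes gave 28 of 74 higher and 0 lower adjusted over the list alone, 0 over all genes, with Rpl15 (1.45 ± 0.29) and Rpl23 (1.61 ± 0.33). Their many processed pseudogenes make single values uncertain. S phase genes gave 6 of 30 higher and 0 lower adjusted over the list alone, 0 over all genes, with Mcm6 (1.29 ± 0.35) and Cdc45 (0.83 ± 0.25). Chaperone genes gave 8 of 20 higher and 1 lower adjusted over the list alone, 0 over all genes, with Cct8 (1.22 ± 0.30) and Cct5 (1.26 ± 0.34), and glycolysis genes 6 of 18 higher and 1 lower adjusted over the list alone, 0 over all genes, with Pgam1 (1.49 ± 0.38) and Pgk1 (1.04 ± 0.29). Of the double positive genes, 2 of 20 were lower adjusted over the list alone, with Arpp21 (-1.03 ± 0.32) and Cd4 (-1.36 ± 0.43). Myc averaged 254 ± 134 against 83.4 ± 85.3 CPM (1.61 ± 0.60, adjusted p = 0.140), and neither it nor Cdc20 (0.36 ± 0.29) nor Trp53 (0.50 ± 0.28) passed. Myc passed by voom with quality weights and without replicate 1. By edgeR 0 genes passed (2719 of 12245 genes had an unadjusted p under 0.05; DESeq2 855, limma voom with quality weights 2125). Replicate 1 decided this count: without it 1549 genes passed (682 higher), and without any other replicate 0 did. The reference group decided it too: without D/AAA DP replicates 1 and 5 (9 left) 1723 genes passed (1121 higher), among them Myc (2.26 ± 0.53), 27 of 31 nucleolar and ribosome biogenesis genes (higher) and 6 of 20 double positive genes (lower). Within block 2 (5 against 6) 736 passed (548 higher).

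Unsorted early tumours (n = 7) were compared with sorted non-tumoral DP cells (n = 11) of the same genotype, so tumour state and the sorted population changed together. The largest rises were in Ccl5 (9.74 ± 1.10), Nkg7 (9.39 ± 0.81), Cd7 (8.88 ± 0.95), H2-Q6 (8.70 ± 1.07), Hbb-bs (8.37 ± 1.46), S100a6 (8.36 ± 1.02), Itgae (8.36 ± 0.85), S100a4 (8.33 ± 1.22), Anxa1 (8.29 ± 1.17) and March8 (8.28 ± 0.65). The T cell and NK cell chemokine gene Ccl5 averaged 2011 ± 1574 against 2.38 ± 1.5 CPM, the cytotoxic granule gene Nkg7 1973 ± 1453 against 2.99 ± 2.80, and the beta globin gene Hbb-bs 1391 ± 3396 against 4.07 ± 4.79. Replicate 3 alone carried the globin mean, with Hbb-bs at 9087 CPM against 108 ± 134 in the other 6, and globin genes at 2.29% of counts against at most 0.0708%. Without it Hbb-bs still passed (4.68 ± 0.94) and Cdc20 passed (-2.17 ± 0.59). H2-Q6 shares sequence with H2-Q7, so its level is uncertain. Hbb-bs did not pass by limma voom with quality weights. The genes BB031773, Lypd6b, Lypd1, Foxb1, Lsmem1 and Pnmal2 had 0 counts in all 7 tumours. Against the floor of 3 counts per library they were lower by at least 105-fold, 26.2-fold, 20.4-fold, 19-fold, 14.4-fold and 12.4-fold, in that order. BB031773 overlaps other genes and the strand protocol is not given, so its counts are uncertain. Falls with counts in both groups were led by Adcy1 (-9.34 ± 0.78), Podxl2 (-8.47 ± 0.68), Xrra1 (-8.38 ± 0.62) and Cpeb1 (-8.32 ± 0.83). Myc rose (1.69 ± 0.49, adjusted p = 0.0132, 7 of 7 above), while Cdc20 (-1.36 ± 0.62, adjusted p = 0.112) and Trp53 (0.46 ± 0.19, adjusted p = 0.0776) did not pass by edgeR. Cdc20 passed by DESeq2, by voom with quality weights and without replicates 2 and 3, each time lower, and Trp53 by voom, within block 2 and without DP replicates 1 and 5 (0.59 ± 0.15), where Cd7 and Lypd1 no longer reached the count filter. Without replicates 2 and 3, the pair nearest to DN3 and DN4, the Myc call ended (1.22) and 5112 genes passed. Among 20 double positive thymocyte genes 18 fell and 0 rose (19 and 0 adjusted over the list alone), with Cd4 (-7.01 ± 0.57) and Slc7a11 (-7.22 ± 0.61). Genes of other cell types rose: of gamma delta T cell genes 7 of 9 rose and 1 fell (8 and 1 adjusted over the list alone), with Tcrg-C1 (5.70 ± 0.55) and Tcrg-C4 (4.77 ± 0.80). The Tcrg-C copies are near-identical. Of NK and innate lymphoid genes 5 of 6 rose and 0 fell (6 and 0 adjusted over the list alone), with Nkg7 (9.39 ± 0.81) and Fcer1g (7.30 ± 0.85), of B cell genes 6 of 7 rose and 0 fell (6 and 0 adjusted over the list alone), with Cd79a (8.24 ± 0.95), and of dendritic cell genes 6 of 6 rose and 0 fell (6 and 0 adjusted over the list alone), with Cd74 (7.41 ± 1.02) and H2-Aa (7.43 ± 1.12). Of interferon response genes 19 of 26 rose and 0 fell (25 and 0 adjusted over the list alone), with Ifi27l2a (5.42 ± 0.69) and Rtp4 (3.55 ± 0.49). Of antigen presentation genes 16 of 19 rose and 1 fell (16 and 1 adjusted over the list alone), and of cytosolic ribosomal proteins 59 of 74 rose and 0 fell (65 and 0 adjusted over the list alone). Of early progenitor genes 3 of 5 rose and 0 fell (4 and 0 adjusted over the list alone), with Irf8 (4.06 ± 0.52) and Mef2c (5.23 ± 1.0). Of G2 and mitosis genes 0 of 30 rose and 3 fell (0 and 0 adjusted over the list alone), with Cenpf (-2.16 ± 0.76) and Nek2 (-2.03 ± 0.71). Without replicate 3 these last counts became 17 of 30 lower (26 adjusted over the list alone), those of early progenitor genes 8 of 9 higher and those of NK and innate lymphoid genes 8 of 9 higher. In all 3468 genes passed, 1894 higher and 1574 lower. Within block 2 (7 against 6) 2852 passed and 2399 of the 3468 were shared with the same sign. Voom with quality weights called 5603. None of the 7 tumours correlated best with the DP stage of +/D cells: 5 were nearest to DN1 (0.904 to 0.936, against at most 0.646 with any other stage) and replicates 2 and 3 to DN3 and DN4. Of the early tumours sorted as DP, 2 were nearest to DP and 3 to DN4.

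**Figure D1:**
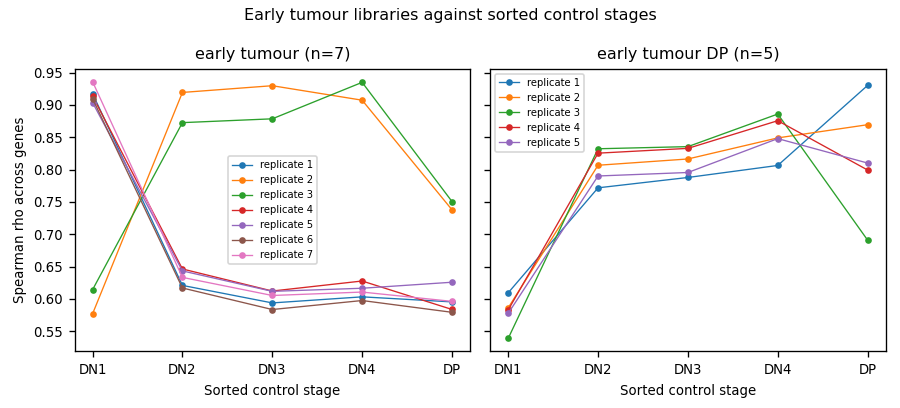
Spearman correlation (vertical axis, no unit) of each early tumour library with the mean of each sorted +/D stage. Each point is 1 library and stage. None of the 7 unsorted tumours is highest at DP.

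Whole thymus labelled non-tumoral was compared between D/AAA (n = 9) and +/D (n = 6) mice. Myc averaged 140.4 ± 90.7 against 54.2 ± 20.1 CPM, above the +/D median in 9 of 9 libraries, but did not pass (1.38 ± 0.36, adjusted p = 0.382). It passed by DESeq2. Cdc20 (0.25 ± 0.27) and Trp53 (0.46 ± 0.19, adjusted p = 0.542) did not pass. Genes of MYC targets and ribosome biogenesis gave 12 of 32 higher and 0 lower adjusted over the list alone, 0 over all genes, with Gnl3 (1.70 ± 0.41) and Dkc1 (0.84 ± 0.23) (camera adjusted p = 1.5e-13, adjusted p = 0.376 with an estimated correlation). Gamma delta T cell genes gave 5 of 8 higher and 0 lower adjusted over the list alone, 0 over all genes, with Tcrg-C1 (1.56 ± 0.44) and Sox13 (1.66 ± 0.47). DN2 and DN3 genes gave 5 of 13 higher and 0 lower adjusted over the list alone, 0 over all genes, with Notch3 (1.18 ± 0.22) and Tcrg-C1 (1.56 ± 0.44) (camera adjusted p = 3.9e-05, adjusted p = 0.0515 with an estimated correlation). Of Notch pathway genes 3 of 12 were higher adjusted over the list alone, with Notch3 (1.18 ± 0.22) and Notch1 (1.29 ± 0.36). Of double positive genes 1 of 20 was lower adjusted over the list alone (Dntt (-0.61 ± 0.16); median of the list -0.54). D/AAA replicates 3, 5, 7 and 8 stood apart, with chromosome 15 gains (scores 0.47, 0.48, 0.56 and 0.30) and Myc at 189.8, 256, 341 and 148 CPM. Of Trbv counts 56.9% lay in Trbv3 in replicate 7, which also had a chromosome 14 gain (0.50), and 41.6% in Trbv16 in replicate 3, against a top share of 21.8% to 27.6% in the other 7. Without replicates 3, 5, 7 and 8 Myc averaged 76.7 ± 16.3 against 53.7 ± 19.9 CPM (0.52 ± 0.22, adjusted p = 0.794), and adjusted over the list alone 0 of 32 MYC target, 0 of 8 gamma delta T cell, 2 of 13 DN2 and DN3, 2 of 11 Notch pathway and 5 of 22 mature thymocyte genes (0 with them) were higher. By edgeR 0 genes passed (907 of 11044 genes had an unadjusted p under 0.05; DESeq2 49, limma voom with quality weights 1), and 0 without the 4 libraries (657 with an unadjusted p under 0.05).

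RERT2 D/AAA tumours (n = 22) were set against D/AAA thymus (n = 9). The largest rises were in Ccn4 (9.41 ± 1.68), Nkd1 (5.47 ± 1.15), Arg1 (4.94 ± 0.86), Stab1 (4.92 ± 0.90), Sh3pxd2b (4.90 ± 1.09), Tln2 (4.64 ± 0.92), Mt2 (4.34 ± 0.95), Lama5 (4.26 ± 1.01) and Mt1 (4.03 ± 0.90). The matrix gene Ccn4 (chromosome 15) averaged 35.2 ± 37.1 against 0.0282 ± 0.0847 CPM, so its fold change is uncertain. The arginase gene Arg1 averaged 6.90 ± 6.77 against 0.227 ± 0.465 CPM, above the thymus median in 22 of 22. The metallothionein genes Mt1 and Mt2 reached 58.9 ± 60.9 and 22.4 ± 24.0 CPM. Zfp532, at 0 counts in the 9 thymus libraries, was at least 6.97-fold higher. The calls of Ccn4, Sh3pxd2b, Tln2, Mt2, Lama5 and Mt1 ended by voom with quality weights, direction kept. The largest falls were in Tdrp (-6.50 ± 0.69), Slc6a19 (-5.92 ± 0.69), Ifi213 (-5.31 ± 0.62), BB031773 (-5.17 ± 0.80), Inpp4b (-5.13 ± 0.64), Ms4a4b (-5.12 ± 0.47), Ifi206 (-4.88 ± 0.73), Tgtp1 (-4.81 ± 0.65) and Zfp827 (-4.79 ± 0.69), each lower in 22 of 22 tumours. Ms4a4b averaged 1.61 ± 1.48 against 56.3 ± 31.8 CPM, and the interferon-inducible Ifi213 1.29 ± 2.09 against 53.6 ± 37.3. Ifi206 and Ifi213, like Tgtp1 and its neighbour 9930111J21Rik1 (-4.85 ± 0.61), are near-identical copies. Cdc20 rose by 0.65 ± 0.23 (adjusted p = 0.0295, 20 of 22 above). Myc (0.22 ± 0.27, adjusted p = 0.569) and Trp53 (0.01 ± 0.22) did not pass, but without the 4 thymus libraries with chromosome 15 gains Myc did (1.10 ± 0.31, 21 of 22 above). In all 4064 of 11634 genes passed, 2109 higher and 1955 lower.

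Genes of MYC targets and ribosome biogenesis, S phase and oxidative phosphorylation rose in the tumours. Of genes of MYC targets and ribosome biogenesis, 27 of 32 rose and 0 fell (30 and 0 adjusted over the list alone), with Nme1 (1.35 ± 0.19) and Odc1 (1.79 ± 0.26). For genes of cytosolic ribosomal proteins, 59 of 74 rose and 0 fell (65 and 0 adjusted over the list alone), with Rpl27 (0.98 ± 0.14) and Rpl38 (0.82 ± 0.13). Of genes of S phase, 25 of 30 rose and 0 fell (27 and 1 adjusted over the list alone), with Mcm4 (1.20 ± 0.20) and Prim1 (0.99 ± 0.17). For genes of G2 and mitosis, 13 of 30 rose and 0 fell (17 and 0 adjusted over the list alone), with Birc5 (0.83 ± 0.18) and Mki67 (0.58 ± 0.14). Of genes of the spindle checkpoint and APC/C, 15 of 34 rose and 1 fell (16 and 1 adjusted over the list alone), with Bub1b (1.38 ± 0.23) and Ube2s (0.91 ± 0.18). For genes of oxidative phosphorylation, 24 of 30 rose and 0 fell (27 and 0 adjusted over the list alone), with Ndufb3 (0.92 ± 0.14) and Cox5b (0.90 ± 0.14). Of genes of glycolysis, 12 of 18 rose and 1 fell (13 and 2 adjusted over the list alone), with Eno1 (1.57 ± 0.19) and Pkm (1.36 ± 0.17). For genes of heat shock and chaperones, 13 of 20 rose and 1 fell (14 and 1 adjusted over the list alone), with Hsp90aa1 (1.55 ± 0.24) and Ahsa1 (1.28 ± 0.20). Of genes of the unfolded protein and integrated stress response, 10 of 24 rose and 1 fell (12 and 1 adjusted over the list alone), with Hsp90b1 (0.79 ± 0.14) and Sdf2l1 (1.28 ± 0.26). For genes of DNA damage response and repair, 12 of 28 rose and 2 fell (13 and 2 adjusted over the list alone), with Fanca (1.12 ± 0.23). Of genes of macrophages and monocytes, 4 of 9 rose and 0 fell (4 and 0 adjusted over the list alone), with Cd68 (1.62 ± 0.41) and C1qc (1.29 ± 0.35). For genes of fibroblasts, 2 of 3 rose and 0 fell (2 and 0 adjusted over the list alone), with Pdgfrb (1.92 ± 0.49) and Fbln1 (1.51 ± 0.51). Without the 4 thymus libraries with chromosome 15 gains 25 of 30 G2 and mitosis genes rose.

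Genes of double positive and mature thymocytes fell, while camera with an estimated correlation called 0 lists of this comparison. Of the listed genes of double positive thymocytes, 0 of 20 rose and 14 fell (0 and 18 adjusted over the list alone), with Bcl6 (-2.15 ± 0.28) and Themis (-1.30 ± 0.18). Among genes of mature and egressing thymocytes, 0 of 22 rose and 17 fell (0 and 18 adjusted over the list alone), with Ms4a4b (-5.12 ± 0.47) and Gimap3 (-4.03 ± 0.41). Among genes of T cell receptor signalling, 0 of 24 rose and 18 fell (0 and 19 adjusted over the list alone), with Lcp2 (-1.46 ± 0.17) and Nfatc3 (-1.39 ± 0.18). Of the listed genes of the interferon response, 1 of 26 rose and 17 fell (2 and 17 adjusted over the list alone), with Ifi27l2a (-4.03 ± 0.53) and Igtp (-1.60 ± 0.22). Among genes of NF-kB and inflammation, 1 of 17 rose and 10 fell (1 and 12 adjusted over the list alone), with Ccl5 (-4.16 ± 0.46) and Ltb (-2.80 ± 0.32). Among genes of T lymphoma oncogenes and suppressors, 2 of 25 rose and 8 fell (2 and 8 adjusted over the list alone), with Ccnd2 (-4.48 ± 0.50) and Dnm2 (-0.89 ± 0.15). Of the listed genes of the Notch pathway, 0 of 13 rose and 3 fell (0 and 3 adjusted over the list alone), with Cdkn1b (-2.16 ± 0.25) and Bcl2l1 (-1.67 ± 0.27). Among genes of DN2 and DN3 cells, 0 of 15 rose and 2 fell (0 and 1 adjusted over the list alone), with Cd7 (-2.54 ± 0.77). Among genes of lysosome and autophagy, 3 of 24 rose and 9 fell (3 and 10 adjusted over the list alone), with Sqstm1 (-0.83 ± 0.11) and Map1lc3b (-0.75 ± 0.14). Of the listed genes of B cells, 0 of 8 rose and 5 fell (0 and 6 adjusted over the list alone), with Pax5 (-3.63 ± 0.75) and Cd22 (-3.31 ± 0.72). Among genes of dendritic cells, 0 of 6 rose and 3 fell (0 and 5 adjusted over the list alone), with Ciita (-2.14 ± 0.51) and Cd74 (-1.53 ± 0.41). Among genes of regulatory T cells, 0 of 6 rose and 5 fell (0 and 5 adjusted over the list alone), with Il2rb (-3.31 ± 0.50) and Tnfrsf4 (-3.14 ± 0.56). Of the listed genes of erythroid cells, 1 of 6 rose and 5 fell (1 and 5 adjusted over the list alone), with Hbb-bt (-2.99 ± 0.69) and Hbb-bs (-2.80 ± 0.68). Among genes of thymic epithelium, 0 of 3 rose and 2 fell (0 and 2 adjusted over the list alone), with Ccl25 (-0.79 ± 0.23) and Cldn4 (-1.92 ± 0.64). Without the 4 thymus libraries with chromosome 15 gains 3 Notch pathway genes rose and 3 fell of 14, and camera with an estimated correlation called 8 lists (S phase, interferon response, double positive thymocyte genes, mature and egressing thymocyte genes, T cell receptor signalling, oxidative phosphorylation, NF-kB and inflammation and regulatory T cells). Lists with both directions were p53 targets, of which 10 of 25 rose and 6 fell (11 and 6 adjusted over the list alone), with Rps27l (1.10 ± 0.21) and Gtse1 (1.10 ± 0.24) and Sesn1 (-0.92 ± 0.17) and Btg2 (-0.95 ± 0.23), and antigen presentation, of which 6 of 19 rose and 10 fell (7 and 10 adjusted over the list alone), with Tapbp (-1.53 ± 0.18) and H2-Q4 (-1.76 ± 0.23). Early progenitor genes gave 1 rise and 1 fall of 7, NK and innate lymphoid genes 1 fall of 5 and gamma delta T cell genes 1 fall of 8, with like counts adjusted over the list alone. Endothelial genes reached the filter in the RERT2 MYCChr6 comparison alone (0 of 3 passed, 1 lower adjusted over the list alone). Adipocyte genes never had 3 members past the filter, and their mean log2(CPM + 1) was 0.403 in these tumours. Over all comparisons camera called 156 of 398 list tests at its preset correlation and 3 with an estimated one: erythroid genes at DN4, gamma delta T cell genes in unsorted early tumours and mature thymocyte genes in LCK D/AAA MYCChr6 tumours. Median, mean and camera had the same sign in every list test that camera called. For the NK and innate lymphoid list in tumours the median was 0.35, the mean -0.46 and the camera direction down (not called). The rotation test fry, which asks whether the members of a list themselves shift, called 97 with direction.

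The share of T cell receptor beta variable (Trbv) counts taken by the most abundant Trbv gene was compared between tumours and thymus, which rises where few T cell clones make up a library, and also where many clones use the same gene. It averaged 73.3% ± 21.7 (SD, n = 19 tumours with at least 100 Trbv counts) and 30.1% ± 11.6 (n = 9) in D/AAA thymus, a difference of 43.2 percentage points (2-sided exact permutation p = 1.8e-05), with 19 of 19 tumours above the thymus median. For alpha variable (Trav) genes the shares were 23.6% ± 19.4 (n = 22) and 6.08% ± 3.14 (n = 9; exact permutation p = 0.0107). Different Trbv genes led in different tumours, 13 over these 19. In +/D thymus, where Trbv13-2 led all 6 libraries, the Trbv share was 24.3% ± 3.60, in tumours labelled p53(+/D) 66.3% ± 23.5 (n = 9), in LCK D/AAA MYCChr6 tumours 73.6% ± 23.9 (n = 14), in LCK +/D MYCChr6 tumours 65.0% ± 20.5 (n = 4) and in RERT2 MYCChr6 tumours 90.6% ± 7.99 (n = 3). Early tumours sorted as DP had 53.3% ± 33.2 (n = 5) against 16.8% ± 14.9 in D/AAA DP cells (n = 11; exact permutation p = 0.00595, 5 of 5 above). Within block 2 the DP cells had 11% ± 0.856 (n = 6; exact permutation p = 0.00866). For Trav genes the early tumours had 12.1% ± 9.21 and the DP cells 6.55% ± 10.7, a difference that did not pass (n = 5 and 11, exact permutation p = 0.346). Sorted +/D DP cells had 11.3% ± 1.42 (n = 7). Unsorted early tumours had 32.0% ± 13.4 (n = 7) and sorted +/D DN1 cells 36.9% ± 5.00 (n = 6). Trbv13-2 led 4 of these 7 tumours and all 6 DN1 libraries, so these shares cannot be read as clone size.

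**Figure D2:**
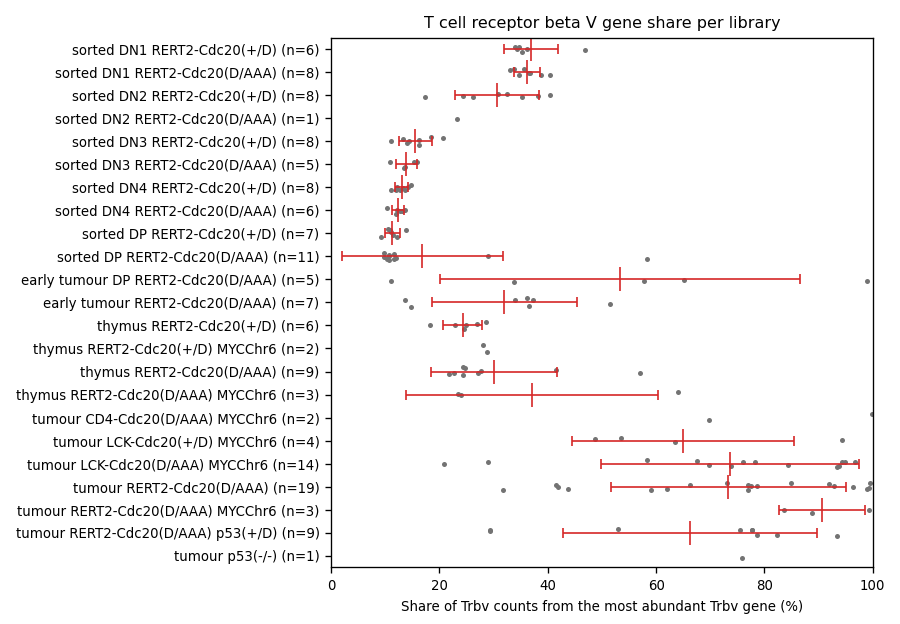
Share of Trbv counts taken by the most abundant Trbv gene (horizontal axis, percent) in each library with at least 100 Trbv counts, by group. Points are libraries, and red marks are means with SD. The 19 RERT2 D/AAA tumours lie between 31.7% and 99.5%.

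Expression by chromosome was measured because the genotype is labelled aneuploid. A chromosome score was the median centred log2 CPM of its genes minus the median over all autosomal genes of the same library. Against D/AAA thymus, RERT2 D/AAA tumours scored higher on chromosomes 14 (0.35, 21 of 22 above, exact permutation adjusted p = 1.3e-04) and 15 (0.32, 22 of 22 above, exact permutation adjusted p = 1.3e-04), and lower on 9 (-0.14), X (-0.15), 19 (-0.09) and 7 (-0.09). Sex is not labelled. In simulated data of this comparison with chromosome 15 alone raised, other chromosomes moved by up to 0.0670. After centring on the scores 3 chromosomes (9, 14 and 15) passed, and 7, 19 and X did not. With genes down to 1 CPM, chromosomes 14 and X no longer passed and 15 did. Scores above 0.292, halfway to the change of 1 extra copy, were counted as gains, against +/D thymus in the later run and against sorted +/D DP cells in the earlier run. On chromosome 15 gains were seen in 22 of 22 RERT2 D/AAA tumours (score 0.57 ± 0.11, SD), 10 of 10 tumours labelled p53(+/D) (0.56 ± 0.13), 4 of 9 D/AAA thymus libraries (0.24 ± 0.22), 9 of 14 LCK D/AAA MYCChr6 tumours (0.48 ± 0.33), 1 of 4 LCK +/D MYCChr6 tumours and 0 of 6 +/D thymus libraries. On chromosome 14 they were seen in 19 of 22 RERT2 D/AAA tumours (0.48 ± 0.16), 10 of 10 tumours labelled p53(+/D) (0.55 ± 0.15), 1 of 9 D/AAA thymus libraries and 2 of 14 LCK D/AAA MYCChr6 tumours (0.06 ± 0.15). With genes down to 1 CPM the first of these counts on chromosome 14 became 6 of 22 and the second 5 of 10, and 89 of the 510 genes were T cell receptor segments, without which the first was 19 of 22. Of all libraries scored, 177 autosomal gains and 1 loss were counted, and 378 gains and 573 losses beyond the reference mean by 3 SD. D/AAA thymus scored 0.24 higher than +/D thymus on chromosome 15 (8 of 9 above) and 0.13 on 14, neither past the test (exact permutation adjusted p = 0.102 for both, n = 9 and 6), and -0.05 on chromosome 5 (exact permutation adjusted p = 0.0320), which ended with genes down to 1 CPM or with centring. No chromosome passed between genotypes at DN1, DN3, DN4 or DP, where chromosome 15 differed by 0.19 at DP (9 of 11 above, exact permutation adjusted p = 0.119) and 2 of 11 D/AAA and 0 of 7 +/D libraries had gains. Early tumours sorted as DP scored higher than D/AAA DP cells on chromosomes 15 (0.46), 14 (0.33) and 4 (0.19), 4 of 5 above on each (exact permutation adjusted p = 0.0353, 0.0321 and 0.0353, n = 5 and 11), and lower on 17 (-0.16), 7 (-0.15) and 6 (-0.14), with 11 chromosomes in all. Without replicate 2, 4 or 5 none passed, without replicate 3 chromosome 15 did not, and within block 2 chromosome 9 alone did. After centring on the scores chromosome 14 alone passed. Gains on 14 and 15 were each seen in 4 of 5 libraries, and with genes down to 1 CPM in 0 of 5 and 4 of 5. Unsorted early tumours scored lower on chromosome 2 (-0.12) and higher on 19 (0.11) and 9 (0.09), exact permutation adjusted p = 0.00817, 0.0126 and 0.0126 (n = 7 and 11). The call of chromosome 9 ended within block 2 and with genes down to 1 CPM, where 5, 11 and 12 passed beside 2 and 19. Sorted +/D DN1 cells, against sorted +/D DP cells, scored -0.10, 0.08 and 0.05 on chromosomes 2, 19 and 9. The gains of the unsorted early tumours were 1 of 7 on 14 and 1 of 7 on 15. Among the 22 RERT2 D/AAA tumours the Myc level did not follow the chromosome 15 score without Myc (Pearson r = 0.118, permutation p = 0.604; Spearman rho = 0.125, p = 0.580; r = 0.269 without the 2 tumours farthest from the median score).

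**Figure D3:**
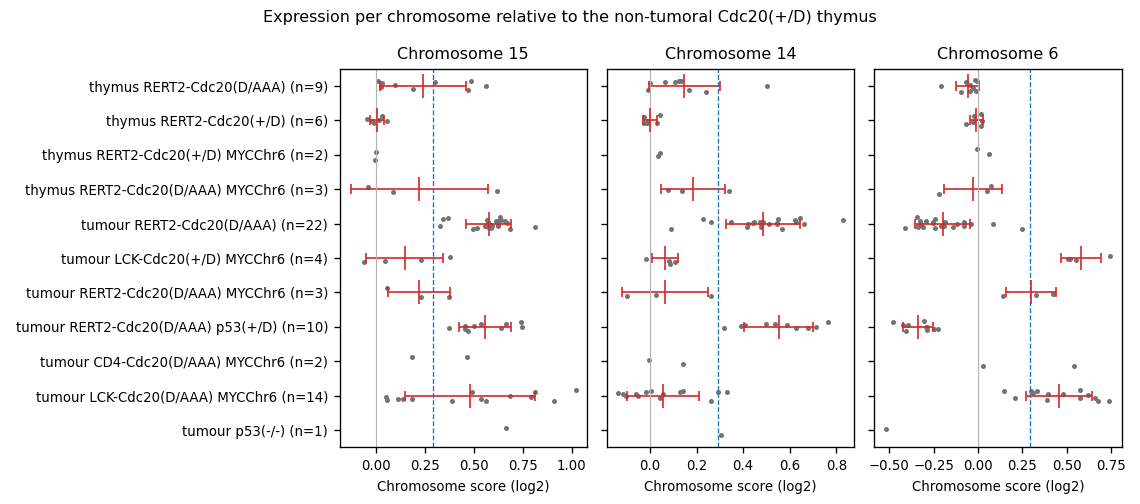
Scores of chromosomes 15, 14 and 6 (horizontal axis, log2) of each library of the later run, by group, against +/D thymus. Points are libraries, red marks are means with SD, and the dashed line marks 0.292. All 22 RERT2 D/AAA tumours lie above it on chromosome 15.

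Tumours labelled RERT2 D/AAA p53(+/D) (n = 10) were set against RERT2 D/AAA tumours (n = 22). Trp53 fell the most, from 174 ± 60.6 to 14.5 ± 7.73 CPM (-3.58 ± 0.29, adjusted p = 3.8e-10, lower in 10 of 10), which is more than the loss of 1 of 2 alleles would give. Other falls were in Rap1gap2 (-2.68 ± 0.69), AA465934 (-2.38 ± 0.31), Psrc1 (-2.33 ± 0.59), Zmat3 (-2.08 ± 0.49), Acadl (-1.84 ± 0.35), Pard6g (-1.71 ± 0.38), Furin (-1.47 ± 0.37), Bag3 (-1.36 ± 0.34) and Pttg1 (-1.35 ± 0.25). Zmat3, a p53 target, averaged 8.34 ± 6.45 against 36.0 ± 32.1 CPM, and Pttg1, which encodes securin, 19.5 ± 5.65 against 50.0 ± 22.6. Rises were in Lypd1 (3.41 ± 0.83), Fstl4 (2.80 ± 0.72), Ahi1 (1.38 ± 0.27), Mettl23 (1.14 ± 0.21), Tmem107 (1.04 ± 0.26), Ndufaf6 (1.02 ± 0.24), Hint2 (0.98 ± 0.26), Mrpl55 (0.91 ± 0.21), Melk (0.88 ± 0.21) and Acot13 (0.79 ± 0.20). The chromosomes of these 10 were 11 for Fstl4, Mettl23, Tmem107 and Mrpl55, 4 for Ndufaf6, Hint2 and Melk, 1 for Lypd1, 10 for Ahi1 and 13 for Acot13. The calls of Lypd1, Fstl4, Tmem107, Ndufaf6, Psrc1 and Pard6g ended by DESeq2, and those of Lypd1, Psrc1, Pard6g and Zmat3 by voom with quality weights. That of Fstl4 also ended without the low-count filter. Of p53 targets 0 of 25 rose and 1 fell (0 and 6 adjusted over the list alone), with Zmat3 (-2.08 ± 0.49) and Bax (-0.57 ± 0.18) (camera adjusted p = 0.0113, adjusted p = 0.972 with an estimated correlation). Of antigen presentation genes 0 of 19 rose and 2 fell (0 and 2 adjusted over the list alone), with Tapbp (-0.91 ± 0.19) and Erap1 (-0.83 ± 0.18). Cytosolic ribosomal proteins gave 3 rises of 74 (8 adjusted over the list alone), with Rpl23a (0.46 ± 0.09) and Rpl22 (0.51 ± 0.11). Cdc20 (0.19 ± 0.19, adjusted p = 0.717) and Myc (0.18 ± 0.21, adjusted p = 0.766) did not pass. In all 148 genes passed, 85 higher and 63 lower. DESeq2 called 361 (176 higher) and voom 459 (320 higher). Chromosomes 4 (0.25), 11 (0.19) and 5 (0.18) scored higher in tumours labelled p53(+/D) (permutation adjusted p = 0.00280, 0.0170 and 0.00280), with 9, 8 and 9 of 10 above the median of the other tumours, and X (-0.21), 6 (-0.13) and 18 (-0.13) scored lower, with 11 chromosomes in all. After centring on the scores 4, 5, 11 and X passed. Gains were seen on chromosome 4 in 8 of 10 p53(+/D) and 3 of 22 RERT2 D/AAA tumours, and on 5 and 11 in 4 of 10 and 4 of 10 against 0 of 22 and 1 of 22. With genes down to 1 CPM chromosome 5 had 0 of 10.

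RERT2 D/AAA MYCChr6 tumours (n = 3) were set against RERT2 D/AAA tumours (n = 22). The largest rises were in Chst2 (9.19 ± 0.65), Nt5e (8.07 ± 0.77), Mzb1 (7.34 ± 0.86), Zfp536 (7.29 ± 0.86), Chn2 (6.86 ± 0.95), Spock2 (6.60 ± 0.77), Jchain (6.52 ± 0.96), Fam84a (6.34 ± 1.02), Pcdh7 (6.27 ± 1.08) and St14 (6.27 ± 0.81). Chst2 averaged 40.8 ± 53.4 against 0.0535 ± 0.128 CPM (102 in replicate 2, 10.2 ± 8.12 in the others), and Nt5e, which encodes CD73, 38.2 ± 17.5 against 0.108 ± 0.365. Mzb1 and Jchain, which B cells and plasma cells express, reached 152 ± 257 and 468 ± 776 CPM (4.35 ± 5.11 and 20.1 ± 21.2 without replicate 3). Without tumour replicate 3 their differences were 2.24 and 1.99 and no longer passed, and without replicate 2 that of Pcdh7 was 3.57 and did not pass. The genes with 0 counts in all 3 MYCChr6 tumours were lower by at least 74.5-fold (Fam163b), 53.9-fold (Ncam1), 38-fold (C78197), 34.8-fold (Slit3), 34.3-fold (F2), 26.8-fold (Heyl), 20.3-fold (Cldn4) and 19.5-fold (Spsb4). C78197 overlaps another gene, so its counts are uncertain. The falls of Col27a1 and Notch3, with counts in both groups, were -10.37 ± 2.62 and -9.51 ± 1.93. All 10 falls ended by voom with quality weights, those of Fam163b and Cldn4 also without the low-count filter, and the rises of Chn2, Fam84a and Pcdh7 by DESeq2. The calls of Fam163b, Ncam1, Col27a1, C78197 and Cldn4 ended without any 1 of the 3 tumours, and that of Slit3 without replicate 1 or 3. Of B cell genes 7 of 9 rose and 0 fell (7 and 0 adjusted over the list alone), with Igkc (7.29 ± 1.08) and Ms4a1 (5.11 ± 0.97). Replicate 3 carried much of this: immunoglobulin genes took 6.57% of its counts and 0.0248% and 0.155% of the others, and without it 4 of 9 B cell genes rose and Igkc did not pass (2.18 ± 1.295, adjusted p = 0.412). Without it antigen presentation genes, counted next, had 4 rises of 19 and mature thymocyte genes 4 of 22. Of cytosolic ribosomal proteins 53 of 74 rose and 0 fell (64 and 0 adjusted over the list alone), with Rpsa (1.0 ± 0.15) and Rplp1 (1.02 ± 0.16). Of antigen presentation genes 12 of 19 rose and 1 fell (13 and 1 adjusted over the list alone), with H2-D1 (2.74 ± 0.32) and H2-K1 (3.59 ± 0.44). Of mature thymocyte genes 8 of 22 rose and 0 fell (10 and 0 adjusted over the list alone), with H2-K1 (3.59 ± 0.44) and Gimap3 (4.27 ± 0.56). Of double positive genes 0 of 20 rose and 9 fell (0 and 12 adjusted over the list alone), with Arpp21 (-8.02 ± 0.71). Of Notch pathway genes 0 of 14 rose and 6 fell (0 and 9 adjusted over the list alone), with Notch3 and Heyl as given above. Myc (-1.01 ± 0.39, adjusted p = 0.114, below in 3 of 3), Cdc20 (-0.37 ± 0.32) and Trp53 (-0.23 ± 0.37) did not pass. In all 1265 genes passed, 775 higher and 490 lower. Without replicate 3 669 passed (417 higher), and voom called 836 (719 higher), DESeq2 1586 (688 higher). Chromosomes 6 (0.37), 10 (0.35) and 19 (0.14) scored higher and 14 (-0.32) and 15 (-0.28) lower in 3 of 3 MYCChr6 tumours (exact permutation adjusted p from 0.0290 to 0.0296, n = 3 and 22). Without replicate 1 or 2 no chromosome passed, without replicate 3 chromosomes 6, 10 and 14 did, and with the trimmed mean chromosome 6 did not.

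LCK D/AAA MYCChr6 tumours (n = 14) were set against RERT2 D/AAA tumours (n = 22), so the driver and MYCChr6 changed together. The largest rises were in F2rl1 (8.84 ± 0.59), Slpi (8.81 ± 1.08), Ccr10 (8.14 ± 0.52), Jchain (7.44 ± 1.08), Sh3bgrl2 (7.31 ± 0.69), Mpo (6.71 ± 0.79), S100a9 (6.58 ± 0.84), Ngp (6.54 ± 0.83), Camp (6.48 ± 0.80) and Spock2 (6.35 ± 0.60). Slpi averaged 272 ± 778 against 0.597 ± 1.15 CPM and Jchain 872 ± 2888 against 5.04 ± 8.06, both above the RERT2 median in 14 of 14. Replicate 9 carried these means: the other 13 averaged 67.8 ± 161 and 102 ± 172 CPM. Mpo, S100a9, Ngp and Camp, all made by granulocytes or their precursors, were on the granulocyte list, of which 5 of 5 rose and 0 fell (5 and 0 adjusted over the list alone). S100a9 averaged 158 ± 244 against 1.51 ± 4.84 CPM (105 ± 144 without replicate 8). Sall3, Spsb4, Stc1 and BC034090 had 0 counts in all 14 LCK tumours and were lower by at least 57.9-fold, 18.9-fold, 11.1-fold and 8.49-fold. Other large falls were in Foxb1 (-8.64 ± 0.83), Ripk4 (-7.19 ± 1.11), Gfra1 (-7.16 ± 0.73), Exoc3l4 (-7.09 ± 0.99), Pdgfrb (-6.95 ± 0.60) and F2 (-6.88 ± 0.60), and the calls of Ripk4 and Gfra1 ended by voom with quality weights. Immunoglobulin genes took 2.96% ± 9.76 of counts in these tumours, with 36.8% in replicate 9 and 0.357% ± 0.524 in the other 13, and 0.0248% ± 0.0248 in RERT2 D/AAA tumours. Without replicate 9 Jchain (4.35 ± 0.72) and Igkc (4.38 ± 0.74) still passed with smaller differences, while Slpi, Ccr10, Mpo and Camp no longer reached the count filter. Of B cell genes 7 of 8 rose and 0 fell (7 and 0 adjusted over the list alone), with Cd22 (4.72 ± 0.63) and Pax5 (4.59 ± 0.67), and of dendritic cell genes 7 of 7 rose and 0 fell (7 and 0 adjusted over the list alone), with Ciita (2.88 ± 0.46) and Cd74 (3.20 ± 0.53). Of mature thymocyte genes 15 of 22 rose and 0 fell (16 and 1 adjusted over the list alone), with Gimap3 (5.25 ± 0.36) and Ms4a4b (5.19 ± 0.47) (camera adjusted p = 1.3e-09, 0.0348 with an estimated correlation). Of NF-kB and inflammation genes 12 of 17 rose and 1 fell (12 and 1 adjusted over the list alone), with Ccl5 (4.06 ± 0.55) and Ltb (2.58 ± 0.35). Of regulatory T cell genes 5 of 6 rose and 0 fell (5 and 0 adjusted over the list alone), with Il2rb (4.81 ± 0.50) and Capg (2.90 ± 0.47). Of Notch pathway genes 1 of 13 rose and 10 fell (1 and 10 adjusted over the list alone), with Ptcra (-6.32 ± 0.78) and Notch1 (-4.83 ± 0.65). Of double positive genes 0 of 20 rose and 12 fell (0 and 13 adjusted over the list alone), with Bcl2l1 (-2.01 ± 0.32) and Aqp11 (-3.14 ± 0.54). Of G2 and mitosis genes 1 of 30 rose and 15 fell (1 and 15 adjusted over the list alone), with Top2a (-0.73 ± 0.13) and Tpx2 (-0.82 ± 0.15). Of T lymphoma oncogenes and suppressors 5 of 25 rose and 10 fell (6 and 11 adjusted over the list alone), with Ccnd2 (5.97 ± 0.42) and Ccnd3 (-2.24 ± 0.28) and Notch1 (-4.83 ± 0.65). Mouse Myc fell by 0.82 on the log2 scale (SE 0.19, adjusted p = 0.00102, below in 14 of 14), to 99.2 ± 30.6 CPM. Cdc20 (-0.43 ± 0.21, adjusted p = 0.107) and Trp53 (-0.13 ± 0.19) did not pass. In all 3934 genes passed, 2071 higher and 1863 lower. Chromosomes 6 (0.48), 3 (0.25), 17 (0.17) and 7 (0.15) scored higher, with 14, 14, 11 and 13 of 14 above, and 14 (-0.41) and 1 (-0.18) lower, with 11 chromosomes in all. The permutation p of 3, 6, 7 and 14 was 1.0e-05 (adjusted p = 5.0e-05), the smallest these permutations can give. Chromosome 15 differed by -0.03 and did not pass (permutation adjusted p = 0.794). Gains against +/D thymus were seen on chromosome 6 in 12 of 14 LCK D/AAA (0.46 ± 0.19) and 4 of 4 LCK +/D MYCChr6 tumours (0.58 ± 0.11), on 12 in 8 of 14 and 2 of 4, and on 3 in 6 of 14 and 0 of 4.

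Among LCK MYCChr6 tumours, D/AAA (n = 14) was set against +/D (n = 4). Granulocyte genes stood higher in D/AAA: 6 of 10 higher and 0 lower adjusted over the list alone, 0 over all genes, with Prtn3 (8.09 ± 2.20) and Camp (5.11 ± 1.81) (camera adjusted p = 0.00102, adjusted p = 0.971 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.20 over 30 members, none past the test on either count (camera adjusted p = 8.8e-05, 0.971 with an estimated correlation). Of the unfolded protein and stress list 0 of 24 passed, led by Phgdh (0.74 ± 0.27) and Atf4 (0.75 ± 0.30). Cdc20 (0.29 ± 0.39), Trp53 (-0.08 ± 0.22) and Myc (-0.05 ± 0.31, +/D replicate 4 at 214.5 CPM, next 77.6) did not pass. By edgeR 0 genes passed (653 of 12791 genes had an unadjusted p under 0.05; DESeq2 19, limma voom with quality weights 0), and 0 without any 1 of the 4 +/D tumours. No chromosome passed. Chromosome 15 differed by 0.34 (12 of 14 above, exact permutation adjusted p = 0.282).

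RERT2 D/AAA MYCChr6 tumours (n = 3) were set against thymus of the same genotype (n = 3). Falls were in H2-T3 (-9.81 ± 0.53), Rag1 (-9.52 ± 0.72), Notch3 (-9.48 ± 0.77) and Dntt (-9.12 ± 0.99). Arpp21 (-8.85 ± 0.94), Ptprf (-8.57 ± 0.96) and Chrna9 (-8.43 ± 0.78) fell too. The recombination gene Rag1 averaged 0.527 ± 0.570 against 419.6 ± 129.8 CPM and Dntt, which encodes terminal transferase, 0.525 ± 0.727 against 317 ± 120.5. Dgkeos, Cldn4 and Fam163b had 0 counts in the 3 tumours and were lower by at least 74.7-fold, 64.2-fold and 24.9-fold. Dgkeos lies opposite another gene, so its counts are uncertain. Rises were in Sccpdh (7.03 ± 1.17), Spock2 (6.31 ± 0.61), Cela1 (5.92 ± 0.96), Pecr (4.14 ± 0.76), Abcb1b (4.12 ± 0.67), Mt1 (3.95 ± 0.64), Fbxw8 (3.93 ± 0.76) and Plac8 (3.55 ± 0.58), and Stra6 and Cdh3, at 0 counts in the 3 thymus libraries, were higher by at least 30.8-fold and 10.5-fold. Of double positive genes 0 of 20 rose and 9 fell (0 and 12 adjusted over the list alone), with Rag1 (-9.52 ± 0.72). Of cytosolic ribosomal proteins 27 of 74 rose and 0 fell (67 and 0 adjusted over the list alone), with Rps2 (1.74 ± 0.18) and Rps13 (2.09 ± 0.24), and of MYC targets and ribosome biogenesis 2 of 32 rose and 0 fell (19 and 0 adjusted over the list alone), with Odc1 (2.53 ± 0.43) and Wdr43 (1.40 ± 0.25). Of Notch pathway genes 0 of 12 rose and 3 fell (0 and 5 adjusted over the list alone), with Notch3 (-9.48 ± 0.77) and Ptcra (-7.52 ± 1.0), and of T cell receptor signalling 0 of 24 rose and 2 fell (0 and 6 adjusted over the list alone), with Nfatc3 (-2.07 ± 0.26) and Lat (-1.51 ± 0.23). Cdc20 (-0.12 ± 0.28), Trp53 (0.58 ± 0.42) and Myc (-0.49 ± 0.54) did not pass. Thymus replicate 1 stood apart, with gains of chromosomes 15 (0.62) and 14 (0.34), 64.0% of Trbv counts in Trbv12-1, Myc at 214 CPM (others 44.0 and 98.1) and Trp53 at 40.4 (others 120 and 115). Without it Myc turned to 0.27 and Trp53 fell to 0.23, with no call. In all 241 genes passed, 102 higher and 139 lower. Single libraries decided this count: without tumour replicate 1, 2 or 3 it was 135, 179 or 163, and without thymus replicate 1, 2 or 3 it was 7, 1 or 1. Of the 20 genes named, the call of H2-T3 alone held without any 1 library. By voom with quality weights the calls of Sccpdh, Pecr, Abcb1b, Fbxw8, Dgkeos, Notch3, Dntt, Fam163b and Arpp21 ended. The chromosome scores were not tested, since 3 against 3 cannot give an exact permutation p under 0.1. Chromosomes 10 (0.38) and 6 (0.36) had the largest differences.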

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

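The tests of the unsorted early tumours, and of Gm10182 against the Cdc20 genotype and a segregating variant, were chosen only after the result was seen. The gene counts within 1 block and without libraries that stood apart, and the chromosome bins with genes down to 1 CPM were likewise added after the data were seen.

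In the 22 RERT2 D/AAA tumours, the lowest of 4 bins of position had a mean score of 0.418 on chromosome 14 and 0.437 on chromosome 15 (genes of at least 10 CPM), which argues against a programme of a few neighbouring genes. With genes down to 1 CPM chromosome 15 kept this (lowest 0.4905), but the lowest bin of chromosome 14 was at -1.04, and 70 of its 128 genes were T cell receptor segments, without which the lowest was 0.408 (chromosome 15: 0.480). Sorted +/D stages reached means of at most 0.0802 (chromosome 14) and 0.121 (15), but in the earlier run, so stage of differentiation stays open. An extra copy stays open as a biological hypothesis, since DNA was not analysed here.

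Gm10182 was at 0 in 54 of 157 libraries and at 1 to 4 counts in 1. The Cdc20 genotype alone is argued against by 21 of 22 RERT2 D/AAA tumours with 5 or more counts. The depth blocks are argued against by block 1, where 16 of 19 D/AAA and 2 of 37 +/D libraries were at 0. A variant or insertion that segregates in the mouse line could give this split into present and absent, with 1 library between. Whether samples share parents is not labelled, so this stays a hypothesis.

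The unsorted early tumours differed from sorted DP cells in 3468 genes, and 0 of the 7 correlated best with sorted +/D DP. By protocol tumours were not sorted unless stated, but 5 libraries correlated best with DN1 (0.904 to 0.936). Trav11 or Trav11d led their Trav counts (30.5% to 64.9%), as in sorted DN1. Cd4 (-7.01 ± 0.57) and Cd8a (-6.78 ± 0.67) lay far below DP cells. All 7 were nearest to DN stages, so the 3468 genes contrast DN-like and DP cells. The blocks as whole cause are argued against by 2399 genes called with the same sign within block 2. An unrecorded sort and a change of the tumour cells stay open and were not tested.

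Among 70 sets of 4 to 10 values, 9 held a value far from the others, where chance gives about 1 in 20. Cdc20 was 111 CPM in D/AAA thymus replicate 7 (others 20.3 to 63.9, n = 9), and the chromosome 14 score of the same library was 0.501 (others -0.01 to 0.24). Trp53 was 357 CPM in sorted DP +/D replicate 1 (others 154 to 212, n = 7), 269 in sorted DN4 D/AAA replicate 6 (others 366 to 394, n = 6) and 0 in the shallow sorted DN1 D/AAA replicate 8 (others 261 to 406, n = 9). Myc was 214.5 CPM in LCK +/D MYCChr6 replicate 4 (others 49.5 to 77.6, n = 4) and 321 in p53(+/D) tumour replicate 5 (others 141 to 223, n = 10). The chromosome 15 score was 0.43 in unsorted early tumour replicate 5 (others -0.03 to 0.12, n = 7). The top Trbv share was 46.9% in sorted DN1 +/D replicate 2 (others 34.0% to 36.1%, n = 6).

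The interaction test of genotype and stage called 22 genes, but 6 of 100 splits reached that count and with DN4 and DP alone 0 genes passed, so a dependence on stage is not shown. In tumours outside the comparisons, scores lay above the highest +/D thymus library: CD4 MYCChr6 replicate 1 had 0.402 on chromosome 10, 0.465 on 15 and 0.486 on 17, replicate 2 had 0.542 on 6, and the p53(-/-) tumour had 0.552 on 4, 0.578 on 5, 0.305 on 14 and 0.662 on 15. The highest control values on these chromosomes were between 0.02 and 0.05.

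Other splits of the same samples were counted, 100 per comparison. Chance was bounded at 1 of 100 (the real split) for unsorted early tumours (3468 genes, highest other 3) and tumours against thymus (4064, 3). So it was for tumours labelled p53(+/D) (148, 1), RERT2 MYCChr6 tumours (1265, 273) and LCK D/AAA MYCChr6 tumours (3934, 22). It was not excluded for the interaction (22, 99, 6 of 100 splits). Nor was it where edgeR called 0 genes and all splits tied. These were DN1 (highest other 3), DN3 (9), early tumours sorted as DP (1), thymus (63) and LCK genotype (435). At DN4 (1, 1, 5 of 100) and DP (1, 206, 6 of 100) any split with 1 gene ties, so the count cannot test Gm10182. The highest other splits at DP, thymus, LCK genotype and interaction exceeded the real counts, which may point to untested sample structure. Of the 99 other splits, 5 (DP), 3 (thymus), 21 (LCK genotype), 75 (interaction) and 59 (RERT2 MYCChr6) called any gene. The DP split with 206 genes parted the blocks at least as much as the real one, and within block 1 the real split gave 5 genes. For RERT2 MYCChr6 tumours against thymus the 10 splits are too few for a share under 0.05 (241 genes, highest other 0).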

How the results depend on the processing

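The analyses within 1 block, without libraries that stood apart (nearest to DN3 and DN4, with chromosome 15 gains, most globin or most immunoglobulin) and without the highest library, the count of losses under other settings and the chromosome bins at 1 CPM were added after seeing the data. No paired analysis was possible because the replicate numbers do not pair samples between groups and no label names a shared animal or litter. The shallowest library, sorted DN1 D/AAA replicate 8, had 21199 counts. In simulated data of the DN1 comparison, with this library, 65% of 4-fold changes were recovered, and of RERT2 MYCChr6 tumours against thymus, with 3 against 3 libraries, 0%. Where a fit left an arm with few samples, edgeR pooled the spread.

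Gene counts that moved by more than 1.5 times were, with DESeq2, 8 (DN1), 13 (DN3), 26 (DN4), 68 (DP), 855 (early tumour DP), 49 (thymus), 361 (p53), 19 (LCK genotype), 1061 (MYCChr6 tumour against thymus) and 97 (interaction). With no low-count filter they were 2, 4 (DN1, DN3), 2 (DP), 16 (early tumour DP), 5531 (unsorted early), 10 (thymus), 552 (p53), 1979 (RERT2 MYCChr6), 7669 (LCK MYCChr6), 2 (LCK genotype), 1185 (MYCChr6 tumour against thymus) and 14 (interaction). With voom and quality weights they were 2 (DN3), 8 (DP), 2125 (early tumour DP), 5603 (unsorted early), 1 (thymus), 459 (p53), 836 (RERT2 MYCChr6) and 362 (MYCChr6 tumour against thymus). One fit of all sorted libraries gave 63, 3, 4 and 255 at DN1, DN3, DN4 and DP. Without the shallow library DN1 had 1, and without DP libraries with chromosome 15 gains early tumour DP had 1723. Within 1 block there were 1 (DN1), 5 (DP), 736 (early tumour DP) and 51 (interaction), and with DN4 and DP alone the interaction had 0. Without the low-count filter the median of all genes moved by -0.43 for RERT2 MYCChr6 tumours. The cause was not tested.

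Shifted chromosomes became 6 at DP with the trimmed mean, 7, 1 and 1 for early tumour DP (1 CPM, centring, within 1 block), 5 for unsorted early tumours (1 CPM), 0 and 0 for thymus (1 CPM, centring), and with centring 3 (tumours), 4 (p53) and 6 (LCK MYCChr6). With the reference mean and 3 SD, gains numbered 378 and losses 573, and with genes down to 1 CPM losses numbered 0 and the lowest bin of chromosome 14 in tumours turned to -1.04. The correlation of Myc with the chromosome 15 score turned to r = -0.0329 with centring. With Trav genes the early tumour DP difference was 5.55 points and no longer passed. Camera called 3 list tests with the correlation estimated, and fry 97. Leaving out 1 library gave ranges of 0 to 4 (DN3 genes), 0 to 1549 (early tumour DP genes), 669 to 1049 (RERT2 MYCChr6 genes), 1 to 179 (MYCChr6 tumour against thymus genes), 0 to 11 (early tumour DP chromosomes) and 0 to 3 (RERT2 MYCChr6 chromosomes). The cause was not tested. The Trbv difference of early tumour DP ranged from 25.2 to 47.1 and LCK genotype and DN3 chromosomes stayed at 0. Of 158 named genes 39 lost their call in a setting and 28 when 1 library was left out. Calls were gained by 6 and reversed in 0.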

Other observations

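The relations of Myc and the double positive list to the chromosome 15 score in thymus and DP cells were not planned and were chosen after the data were seen, and the other tests of this part had their predictions written before their results. A clone with a chromosome 15 gain that grows could raise the top Trbv share with the score. Over 6 relations, the Pearson r was 0.654 in D/AAA thymus (n = 9, exact permutation p = 0.0366, adjusted p = 0.0366; rho = 0.167, exact permutation p = 0.678; r = 0.641 without 2 libraries, exact permutation p = 0.129) and 0.925 in sorted DP D/AAA cells (n = 11, permutation adjusted p = 0.00388; rho = 0.464, permutation p = 0.156; r = 0.108 without 2 libraries). The ranks did not follow, and 2 libraries carried the second relation, so the data leave this open.

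In the same libraries Myc followed the chromosome 15 score without Myc in D/AAA thymus (r = 0.963, exact permutation adjusted p = 4.5e-04; rho = 0.983, adjusted p = 3.0e-04; r = 0.926 without 2, n = 9) and in sorted DP D/AAA cells (r = 0.828, permutation adjusted p = 4.6e-04; rho = 0.846, adjusted p = 0.00642; r = 0.789 without 2, n = 11). The double positive list ran against the score, with r = -0.831 (rho = -0.867, without 2 r = -0.936) in thymus and r = -0.876 (rho = -0.809, without 2 r = -0.653, permutation p = 0.0606) in DP cells. Cell stage and copy number were not separated.

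Of the genes tested on chromosomes 14 and 15, 30.4% were higher in RERT2 D/AAA tumours than in D/AAA thymus (17.3% on the other autosomes), and on chromosomes 4, 5 and 11, 2.73% were higher in tumours labelled p53(+/D) (0.21% elsewhere). These chromosomes were picked for their higher scores in the same libraries, so the shares restate the scores and decide nothing about gene dosage, which stays open.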
